A study of Mus musculus with 8 samples.

How the data were processed

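Gene expression was measured in CD4+ T cells sorted by EGFP fluorescence from mice carrying an EGFP-tagged wild-type or mutant Foxp3 allele, 1 Affymetrix array per sample and 8 samples in all. Per the labels' protocols, RNA was extracted with RNEasy and labelled with biotin by the Affymetrix method. The deposited values are probe set intensity on a linear scale, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, applies quantile normalization and summarises the probes of a set. The software version, and whether all arrays were processed in 1 run, are not given in the sources used here. The array medians, between 53.3 and 54.8, fit a common scale, and no array was left out. Probe-level data, detection calls and scan dates were not used here, so low values carry no detection call and are described by their percentile. RMA compresses differences at low intensity, so differences from groups of low intensity may be understated.

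The file held 45101 probe sets; 64 control probe sets were left out and 45037 tested without a filter. The platform annotation given with the data named 1 gene symbol for 34945 probe sets, several for 932 and none here for 9160, and 34741 were matched to a current gene record, whose symbol was used. Probe sets with several symbols were not named, apart from that of Trgv4 with Trgv2 among the interaction calls. The 18193 genes with a probe set were each represented by the probe set with the highest mean over all arrays, and disagreement of other probe sets is stated. Log2 was taken of the intensities without a pseudocount.

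A mean per group was fitted with limma 3.58.1 in R 4.3.3 to all 8 arrays, with 4 residual degrees of freedom, all from the EGFP-positive groups, and 3.72 prior degrees of freedom from eBayes. Tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets of a comparison and a threshold of 0.05; printed adjusted p-values of genes come from this fit. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1. The tested comparisons were mutant against WT EGFP-positive, EGFP-positive against EGFP-negative for each allele, and the interaction; the single EGFP-negative arrays were compared by values alone. Groups, comparisons, tests, gene lists, the naming rule and most alternatives were fixed before the data were examined.

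Gene lists of 632 symbols were fixed, 565 of them measured: genes known to be high or low in regulatory T cells, Th1, Th2, Th17, follicular helper, cytotoxic, suppressor, early activation, dissociation stress, naive and quiescent, cell cycle, T cell receptor signalling, homing, interferon response, IL-2 and STAT5 target, glycolysis, oxidative phosphorylation, apoptosis, cytokine receptor, costimulatory and coinhibitory, ribosomal protein and control genes, and markers of B cells, myeloid cells, CD8 T cells, NK cells, erythroid cells and platelets, immature thymocytes and stroma. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry; lists with fewer than 5 measured genes were given as values only. Members were counted after adjustment over all probe sets and adjusted over the list alone. For the single EGFP-negative arrays a list's median was ranked among 10000 random lists matched on mean level. Foxp3 belongs to the first list and to the IL-2 and STAT5 list, and other genes too belong to more than 1 list. The NK cell list shares Gzma and Eomes with other lists, while the 2 CD8 T cell genes are in no other.

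The genes named were a fixed panel (Foxp3, Il2ra, Ctla4, Ikzf2, Tnfrsf18, Il7r, Pde3b, Satb1, Il2, Ifng, Il4, Il10, Gzmb, Gata3 and Tbx21; a further item is not reported here), the 10 highest and 10 lowest past the threshold with non-overlapping arrays, and per list up to 4 members past the threshold by size or, where none passed, up to 2 with the smallest p. Non-overlapping arrays were a condition for naming the 10 highest and 10 lowest, so they add no evidence for those genes. For the interaction and the EGFP-negative arrays the panel and the 5 highest and 5 lowest were taken, the latter in the upper part of mean level.

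The fit was tested on simulated arrays with 200 of 45037 probe sets changed. For mutant against WT EGFP-positive it recovered 80.3% of 2-fold, 98.6% of 4-fold and 98.3% of 8-fold changes, with 21 false calls. For the WT EGFP comparison these were 32.3%, 97.3% and 98.4% (16 false calls), for the mutant EGFP comparison 16.9%, 100% and 100% (10), and for the interaction 0%, 73.2% and 100% (6). With the cell cycle list raised by 0.5 in simulated arrays of 18193 genes, camera gave an adjusted p of 1.1e-33 and called 0 of 28 other lists. Simulated genes varied independently of each other, while the correlation estimated for that list in the real arrays was 0.621. False calls from genes that vary together could therefore not arise in the simulation.

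Alternatives were a filter on the lowest 40% of probe sets by mean, repeated quantile normalization, median centring, cyclic loess, eBayes with trend and robust settings, array weights, the leading digits of the sample titles as a block or random block, each replicate left out, a 2-fold threshold, gene means over probe sets, only the arrays of a comparison, and a pseudocount of 16. Leaving out a pair of arrays with a low mean of the stress list, and covariates for the stress list and for Xist, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.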

Results

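Gene expression was measured on 8 Affymetrix oligonucleotide arrays, each from sorted mouse CD4+ T cells. The mice, hemizygous males per the study's design text where it speaks of EGFP-positive cells, carried an allele of Foxp3, the X-linked transcription factor that defines regulatory T cells, tagged with enhanced green fluorescent protein (EGFP). The allele was either wild type or a mutant named delta in the labels, and cells had been sorted by EGFP fluorescence. The groups were arrays labelled WT EGFP-positive (n = 3), mutant EGFP-positive (n = 3), WT EGFP-negative (n = 1) and mutant EGFP-negative (n = 1). Median intensity per array lay between 53.3 and 54.8. Across probe sets, log2 values correlated at 0.98 to 0.9918 within the WT EGFP-positive group, at 0.9879 to 0.9912 within the mutant EGFP-positive group and at 0.9601 to 0.9688 between these groups. The number of arrays limits the precision of every value below. No source used here says that replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical. All differences are on the log2 scale. For single genes a fold is printed only where the means of both groups lay above the median of all probe sets, since values carry no detection call here. Further, each single EGFP-negative array was assumed to vary like the replicated groups.

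The targeted gene, Foxp3, was read first in every array. Its probe set stood at 4.75 ± 0.11 (SD, n = 3) in the arrays labelled WT EGFP-positive and at 4.52 in the array labelled WT EGFP-negative, a difference of 0.24 (SE 0.2, limma adjusted p = 0.82). Within the WT EGFP-positive arrays it ranked between the 24.8 and the 31.3 percentile of all probe sets. It stood at 6.14 in the mutant EGFP-negative array and at 11.28 ± 0.21 (SD, n = 3) in the mutant EGFP-positive arrays. The low reading in the WT EGFP-positive arrays goes against their label. The position of this probe set relative to the altered part of either allele is not given in the sources used here. Without that position the readings could not settle which allele an array holds. Groups are therefore named as their arrays are labelled, and every direction between alleles below rests on those labels.

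**Figure D1:**
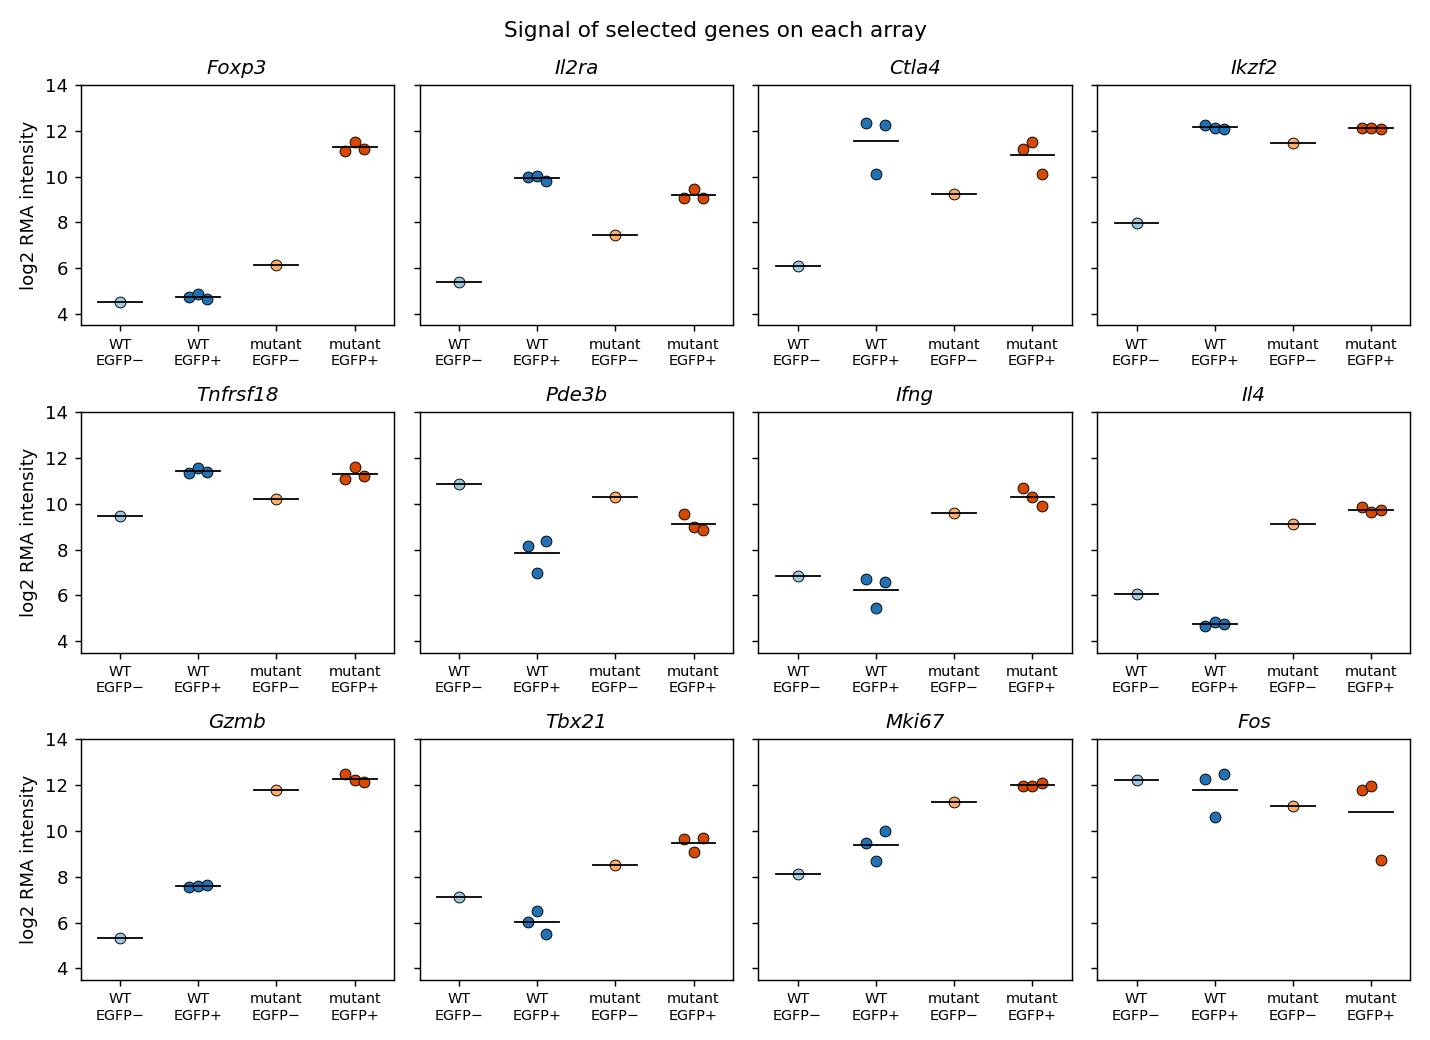
Log2 expression of genes of the fixed panel, and of Mki67 and Fos from outside it (vertical axis, log2 intensity), in each array. The horizontal axis gives the labelled group, points are single arrays and horizontal bars are group means. Foxp3 reads 4.75 on average in the WT EGFP-positive arrays and 11.28 in the mutant EGFP-positive arrays, while Ikzf2 reads 12.16 and 12.11.

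The comparison of mutant with WT EGFP-positive cells asks what differs with the mutant allele in cells labelled as sorted EGFP-positive. In the arrays labelled mutant EGFP-positive, Gzma, a granule protease of cytotoxic lymphocytes, rose from 5.56 ± 0.24 to 11.74 ± 0.33 (SD, n = 3 each; difference 6.18, SE 0.19). Gzmb, a related protease, rose 25.8-fold, from 7.6 ± 0.04 to 12.28 ± 0.18 (difference 4.69, SE 0.12). The cytokine genes Il4 and Ifng rose by 5.01 (SE 0.11) and 4.05 (SE 0.35), Ifng 16.5-fold. Il4 stood at 4.74 ± 0.09 (SD, n = 3) in the WT arrays, as low as Foxp3. H2-Ob, a subunit of a class II antigen-loading regulator, fell by 4.63 (SE 0.31). Foxp3 itself rose by 6.52 (SE 0.14), with the reservation about its probe set given above. In limma's moderated test the adjusted p was 1.4e-05 for Gzma, 6.9e-06 for Gzmb, 3e-06 for Il4 and Foxp3, 0.00045 for Ifng and 2e-04 for H2-Ob, and for each of these all 3 mutant arrays lay on the same side of all 3 WT arrays.

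Other genes with the largest rises were Epas1, a hypoxia-inducible transcription factor (5.81), the chemokine Ccl3 (5.2), the chemokine receptor Cxcr6 (5.13), the protease Gzmk (4.75), the kinase Rps6ka6 (4.27) and the desmosomal cadherin Dsg2 (4.26). The largest falls after H2-Ob were in Prg4, which encodes a lubricating proteoglycan (-4.14), the cytochrome P450 gene Cyp4f18 (-3.5), the heat shock gene Hspa1b (-3.45), Cd55, a regulator of complement (-3.44), Atp1b1, a subunit of the sodium pump (-3.15), the stress-responsive gene Sesn1 (-3.13), Ntn4 (-2.92), the heat shock co-chaperone Dnajb4 (-2.85) and the receptor Gpr34 (-2.8). A further probe set of Cyp4f18 differed by -0.03, and the calls of Hspa1b and Dnajb4 depended on single arrays, as described with the stress genes below. Of the remaining panel genes, Tbx21, the master regulator of Th1 cells, rose by 3.46 (SE 0.27, limma adjusted p = 0.00031), and Il2 by 1.07 (SE 0.14, 0.0026) from low levels of 4.2 to 5.27. Il2ra, the alpha chain of the IL-2 receptor, fell by 0.75 (SE 0.14, adjusted p = 0.012), a call lost without WT EGFP-positive replicate 1 (0.051) or mutant EGFP-positive replicate 1 (0.053), within a range of 0.0026 to 0.062 over all alternatives. Several genes typical of regulatory T cells did not pass: Ikzf2 differed by -0.05 (SE 0.1, adjusted p = 0.83), Tnfrsf18 by -0.12 (SE 0.16, 0.73) and Ctla4 by -0.61 (SE 0.61, 0.63). Ctla4 differed by -1.34 without WT EGFP-positive replicate 2 (adjusted p = 0.043; 0.007 to 0.91 over the alternatives), and its direction turned, to 0.7, with the mean of the stress list as a covariate (0.2). Il7r differed by -0.66 (0.45), and by -1.23 without mutant EGFP-positive replicate 2 (0.031; 0.031 to 0.81 over the alternatives). Pde3b differed by 1.3 (0.057), and by 0.87 without WT EGFP-positive replicate 2 (0.032; 0.0082 to 0.19). Il10 differed by 1.15 (0.44), by 0.2 without WT EGFP-positive replicate 2 (0.84) and by 2.81 with the stress covariate (0.0045). Without WT EGFP-positive replicate 2 and mutant EGFP-positive replicate 3 together Il10 differed by 0.7 (0.026). Satb1 differed by -0.29 (0.24). Gata3 differed by 0.43 (0.36), and by 0.12 without mutant EGFP-positive replicate 2 (0.73; 0.16 to 0.73).

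Genes of the cell cycle rose together in the mutant EGFP-positive arrays. Of 48 measured members 47 rose and 0 fell (48 and 0 adjusted over the list alone), with a median difference of 2.56. Examples were the spindle checkpoint kinase Bub1 (3.55), the mitotic kinase Aurkb (3.41), the cyclin Ccna2 (3.31) and the cyclin-dependent kinase Cdk1 (3.27). In limma's camera test with a preset correlation the adjusted p was 1.5e-36, and adjusted p = 0.17 with an estimated correlation, so that call was lost. Of 19 glycolysis genes 11 rose and 1 fell (13 and 1 adjusted over the list alone), among them Tpi1 (2.36), Hk2 (1.41), the lactate carrier Slc16a3 (1.32) and Pgam1 (1.19), with camera adjusted p = 6.9e-06 and adjusted p = 0.16 with an estimated correlation. Of 38 genes of oxidative phosphorylation 15 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 0.4 (camera adjusted p = 3.1e-08, and adjusted p = 0.2 with an estimated correlation). The examples Ndufb9 (0.72) and Ndufb8 (0.71), both subunits of respiratory complex I, each had a further probe set that differed the other way (-0.19 and -0.24), and Ndufb8 lost its call without mutant EGFP-positive replicate 1 (adjusted p = 0.052; 0.0041 to 0.26 over the alternatives).

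Of 27 measured cytotoxic genes 17 rose and 1 fell in the same arrays (17 and 2 adjusted over the list alone), led by Gzma, Ccl3, Gzmk and Gzmb (camera adjusted p = 2.3e-10, and adjusted p = 0.16 with an estimated correlation). Cd8a, which marks another T cell subset, stood at 8.5, 8.84 and 5.95 in the mutant EGFP-positive arrays and at 6.36, 5.22 and 6.29 in the WT EGFP-positive arrays. It differed by 1.81 (SE 0.71, adjusted p = 0.16), and by 2.71 without mutant EGFP-positive replicate 3 (adjusted p = 0.0055; 0.00017 to 0.4 over the alternatives). Its partner Cd8b1 differed by 0.05 (SE 0.23, 0.94). Of 16 Th1 genes 11 rose and 0 fell (12 and 1 adjusted over the list alone), including Cxcr6, Ccl5 (4.06), Ifng and Tbx21 (camera adjusted p = 3e-07, and adjusted p = 0.16 with an estimated correlation). Of 14 genes of follicular helper T cells 6 rose and 1 fell (8 and 2 adjusted over the list alone), among them the cytokine Il21 (3.67), Tox2 (2), Pou2af1 (1.76) and the inhibitory receptor Pdcd1 (1.53). The camera adjusted p of that list was 0.0066, with adjusted p = 0.26 with an estimated correlation and 0.058 without mutant EGFP-positive replicate 3. It was 0.057 without that array and WT EGFP-positive replicate 2 together. Further probe sets of Il21 and Tox2 differed by 0.07 and 0.04.

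Genes of naive and resting T cells moved downward. Of 17 measured members 11 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -1.26 (camera adjusted p = 3e-09, and adjusted p = 0.16 with an estimated correlation). They included the transcription factors Foxo1 (-1.81) and Bach2 (-1.74), which maintain quiescence, and the antiproliferative gene Tob1 (-2.04), which lost its call without WT EGFP-positive replicate 1 (adjusted p = 0.051; 0.00054 to 0.051 over the alternatives). Ccr7, the lymph node homing receptor, differed by -1.59 (adjusted p = 0.042) and lost its call when any single EGFP-positive array except WT replicate 2 was left out (up to 0.14; 0.00032 to 0.22 over the alternatives). Of 25 genes known to be low in regulatory T cells 12 fell and 4 rose (12 and 5 adjusted over the list alone), Prg4 and Atp1b1 falling and Ifng rising (camera adjusted p = 1.6e-05, and adjusted p = 0.16 with an estimated correlation). Of 33 genes of T cell receptor signalling 9 fell and 3 rose (11 and 4 adjusted over the list alone); the adaptor Grap2 fell by 1.04, while the kinase Zap70 (1.05) and the signalling protein Themis (1.29) rose (camera adjusted p = 0.0014, and adjusted p = 0.16 with an estimated correlation). Of 27 cytokine receptor genes 10 fell and 5 rose (12 and 6 adjusted over the list alone): Il6ra differed by -2.51, the decoy receptor Il1r2 by 2.67 and Il18rap by 2.04 (camera adjusted p = 0.01, and adjusted p = 0.16 with an estimated correlation).

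Of 46 genes known to be high in regulatory T cells, 11 rose and 11 fell (12 and 13 adjusted over the list alone). Besides Foxp3 and Gzmb, the opioid precursor Penk (2.79) and the cytokine subunit Ebi3 (2.74) rose. The list's median was -0.05 and its mean 0.28; camera ranked it downward (adjusted p = 0.87), while fry, which tests whether the genes move one way on balance, gave upward (adjusted p = 0.0031). Of 17 genes tied to suppressor function 8 rose and 4 fell (9 and 4 adjusted over the list alone), with Lag3 at 2.33 and the integrin Itgae at -1.73 (camera adjusted p = 0.065, and 0.032 without WT EGFP-positive replicate 1 or 0.038 without mutant EGFP-positive replicate 3). Itgae lost its call without WT EGFP-positive replicate 1 (0.066) or mutant EGFP-positive replicate 1 (0.061; 0.0029 to 0.077 over the alternatives).

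Of 21 immediate-early and heat shock genes, a list fixed as a sign of cell handling, 5 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.93 (camera adjusted p = 0.00074, and adjusted p = 0.53 with an estimated correlation). Fry did not call it (0.11). Hspa1b stood at 9.11, 10.75 and 7.74 in the WT EGFP-positive arrays, and its fall (adjusted p = 0.014) did not pass without WT EGFP-positive replicate 1 (0.053; 0.0037 to 0.053 over the alternatives). Dnajb4 did not pass without that array or without mutant EGFP-positive replicate 2 (0.056 each; 0.00021 to 0.056 over the alternatives). The mean of the list differed between arrays of one label: 10.79, 9.73 and 10.83 in the WT EGFP-positive arrays and 9.99, 9.96 and 8.87 in the mutant EGFP-positive arrays.

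In all, limma called 5734 of 45037 probe sets (12.7%) between the EGFP-positive groups, 3308 higher and 2426 lower in the arrays labelled mutant; 1974 of them differed at least 2-fold. By gene, 1897 were higher and 1096 lower. The balance of directions depended on the arrays: 3791 were higher and 3765 lower without WT EGFP-positive replicate 2, and 3630 higher and 4342 lower without that array and mutant EGFP-positive replicate 3, which were chosen after seeing the data as the lowest of their groups in the mean of the stress list. The count was 3355 without WT EGFP-positive replicate 1, 3356 without mutant EGFP-positive replicate 1 and 3716 without mutant EGFP-positive replicate 2, and 3810 with the mean of the stress list as a covariate. Of the 29 lists tested camera called 11 with the preset correlation and 0 with an estimated one, with 8 at an unadjusted p under 0.05. Fry called 20. The estimated correlation was -0.004 for T cell receptor signalling and -0.025 for cytokine receptors, under the preset 0.01. A larger correlation therefore did not cost those lists their calls.

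**Figure D2:**
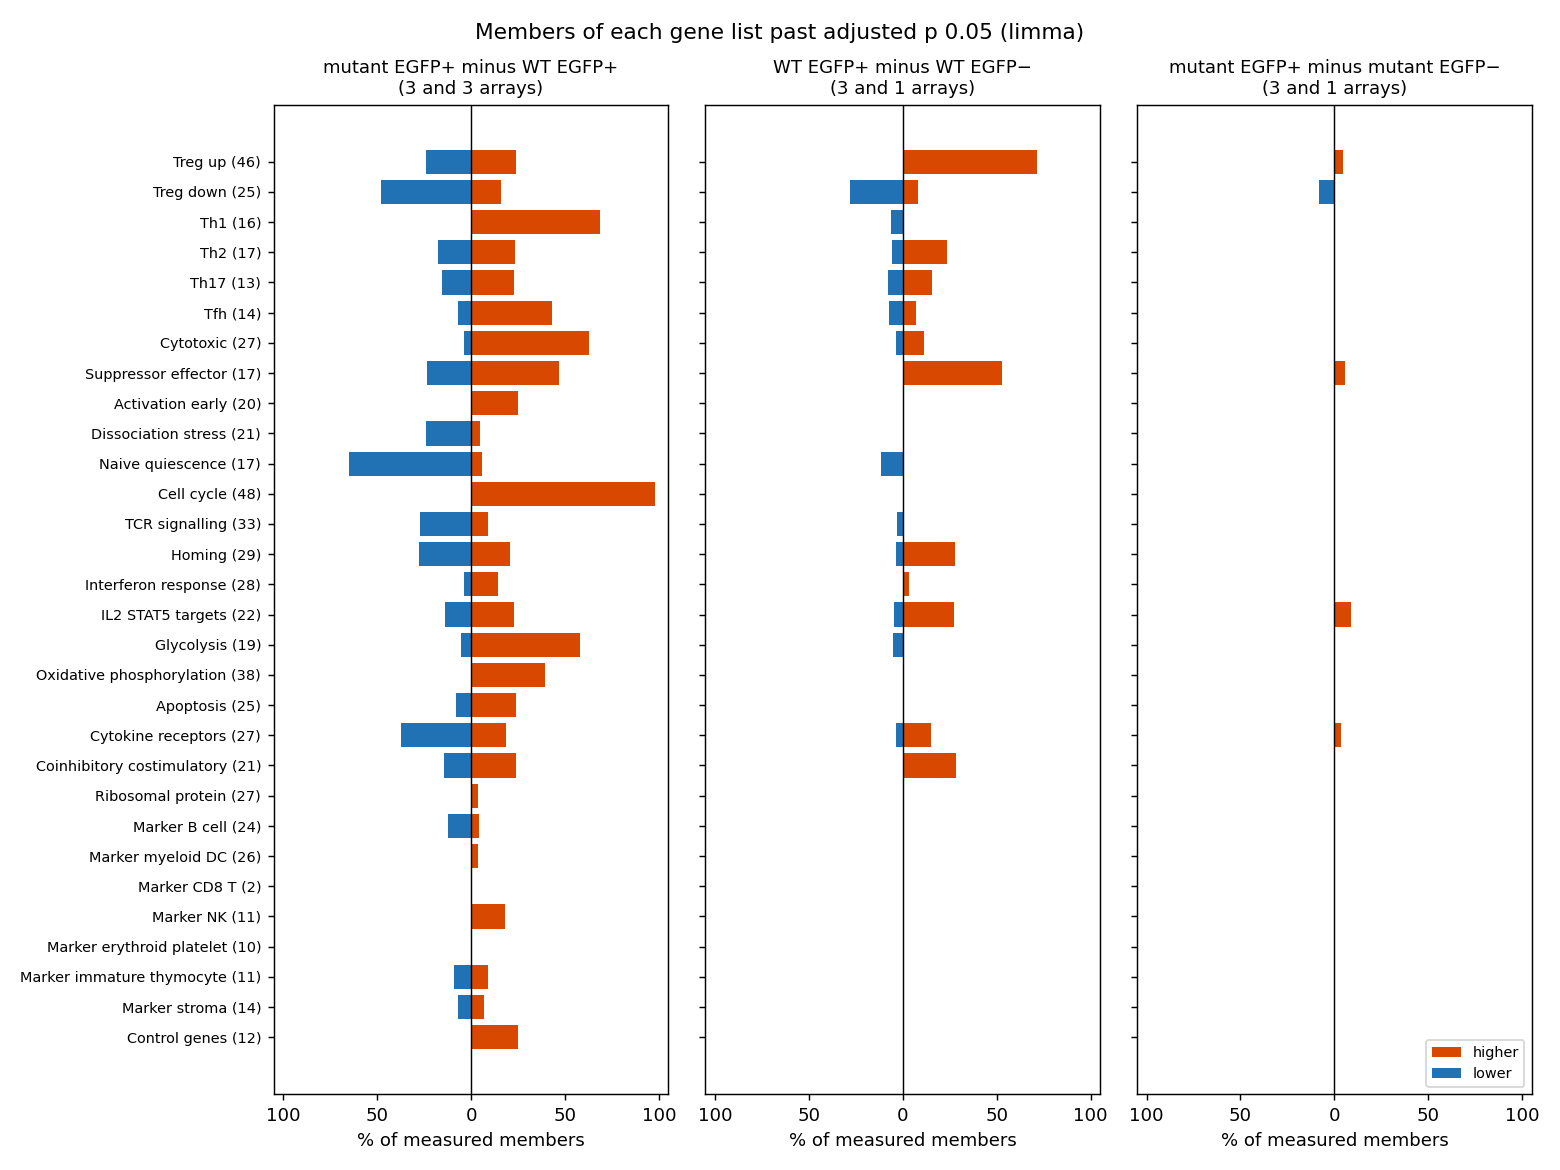
Percent of the measured members of each fixed gene list (vertical axis) that limma called (horizontal axis). Members called higher are drawn as positive and members called lower as negative percentages. The comparisons are mutant minus WT EGFP-positive, and EGFP-positive minus EGFP-negative for each allele. Of 48 cell cycle genes 47 were called higher for mutant minus WT EGFP-positive. Of 46 genes known to be high in regulatory T cells 33 were called higher for WT EGFP-positive minus WT EGFP-negative.

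The comparison of EGFP-positive with EGFP-negative cells of the wild-type allele describes the cells labelled as sorted EGFP-positive. Ikzf2, a transcription factor typical of regulatory T cells, rose 18.1-fold, from 7.98 in the WT EGFP-negative array to 12.16 ± 0.09 (SD, n = 3; difference 4.18, SE 0.15, limma adjusted p = 0.00018). Il2ra rose from 5.38 to 9.94 ± 0.11 (SD, n = 3; difference 4.56, SE 0.2, 0.00048). Itgae rose by 5.1 (SE 0.51, 0.0057), the activation marker Cd83 by 4.51 (SE 0.25, 0.00092), and the costimulatory receptor Tnfrsf4 by 3.41 (SE 0.19, 0.00092). Pdlim4, which encodes a cytoskeletal adaptor, fell 23.5-fold (difference -4.56, SE 0.22, 5e-04). All 3 EGFP-positive arrays lay on the same side of the single EGFP-negative array for each of these genes, while the Foxp3 probe set did not pass (0.24, 0.82).

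Further large rises were in the receptors Klrg1 (3.85) and Nrp1 (3.78) and in Ntn4 (3.75); in the panel, Gzmb rose by 2.29 (adjusted p = 0.0022) and Tnfrsf18 by 1.96 (0.0087). Ctla4, an inhibitory receptor that blocks costimulation, differed by 5.48 (SE 0.87, 0.031), but its call was lost without WT EGFP-positive replicate 1 (0.087) or 3 (0.096) and without mutant EGFP-positive replicate 1 (0.09) or 2 (0.064), within 8e-05 to 0.17 over the alternatives. The same held for the phosphatase Dusp4 (4.87; 0.051, 0.059, 0.059 and 0.052 without the same arrays; 8e-05 to 0.14 over the alternatives) and for Plagl1 (4.6), which did not pass without any of the EGFP-positive arrays except WT replicate 2 (up to 0.1; 8e-05 to 0.21 over the alternatives) and whose other probe sets differed by 0.58 to 1.38. The largest falls after Pdlim4 were in Atp8b4 (-3.88), Dapl1 (-3.56), the NK receptor gene Klrd1 (-3.17), Lrrc75b (-3.13), Cxcr6 (-3.11), Lypd6b (-2.97), the phosphodiesterase Pde5a (-2.77) and the neuropeptide receptor Vipr1 (-2.56). The calls of Atp8b4, Dapl1, Klrd1 and Cxcr6, and that of Il4 below, held without any single EGFP-positive array but were lost under another alternative. Pde3b, a phosphodiesterase known to be low in regulatory T cells, differed by -3.04 (0.04) and did not pass without any of the EGFP-positive arrays except WT replicate 2 (up to 0.092; 0.002 to 0.18 over the alternatives). Il4 fell by 1.34 (0.0095). Il7r (-1.41), Satb1 (-0.62), Il2 (-0.74), Ifng (-0.61), Tbx21 (-1.1) and Gata3 (0.61) did not pass, and neither did Il10 (2.62, 0.51), which differed by 3.57 without WT EGFP-positive replicate 2 (0.022; 0.00034 to 0.82 over the alternatives).

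Of 46 genes known to be high in regulatory T cells 33 rose and 0 fell (42 and 0 adjusted over the list alone), with a median of 2.47; limma's camera gave an adjusted p of 6.8e-71, which held with an estimated correlation (adjusted p = 0.0051). The calls of 5 further lists held as well. Of 25 genes known to be low in these cells 7 fell and 2 rose (13 and 2 adjusted over the list alone), including Dapl1 and the receptor Tgfbr3 (-2.2), while Prg4 rose by 2.72 (camera adjusted p = 2.9e-08, and adjusted p = 0.048 with an estimated correlation). Of 17 suppressor genes 9 rose and 0 fell (11 and 1 adjusted over the list alone; 1.3e-15, and adjusted p = 0.043 with an estimated correlation). Of 29 homing genes 8 rose and 1 fell (10 and 1 adjusted over the list alone; 2.9e-08, and adjusted p = 0.04 with an estimated correlation), the chemokine receptor Ccr6 rising by 2.66 and Cxcr6 falling. Of 22 targets of IL-2 and STAT5 signalling 6 rose and 1 fell (9 and 2 adjusted over the list alone; 5e-07, and adjusted p = 0.04 with an estimated correlation), among them the IL-2 receptor chain Il2rb (2.74) and the signalling inhibitor Socs2 (3.07). Of 21 costimulatory and coinhibitory receptor genes 6 rose and 0 fell (11 and 0 adjusted over the list alone; 5.3e-10, and adjusted p = 0.029 with an estimated correlation), with Tnfrsf9 at 2.72.

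Lists whose call was lost with an estimated correlation were cytokine receptors (4 rose and 1 fell; 9 and 3 adjusted over the list alone; camera adjusted p = 0.00098, and adjusted p = 0.058 with an estimated correlation). The same was true of Th2 genes (4 rose and 1 fell; 6 and 1 adjusted over the list alone; 0.00074, and adjusted p = 0.12 with an estimated correlation), Th17 genes, where Ahr rose by 2 and Il21 fell by 1.28 (0.01, and adjusted p = 0.34 with an estimated correlation), and follicular helper genes, where Icos rose by 1.69 (0.034, and adjusted p = 0.38 with an estimated correlation). In the cell cycle list limma called 0 of 48 genes (2 adjusted over the list alone, 15 higher and 1 lower at an unadjusted p under 0.05) although its median was 0.71 (1.9e-09, and adjusted p = 0.5 with an estimated correlation). The apoptosis list had 0 calls of 25 (2 adjusted over the list alone, 8 higher and 1 lower unadjusted; 0.00098, and adjusted p = 0.058 with an estimated correlation). The naive list had 2 falls, Dapl1 and Igfbp4 (-2.03), with camera adjusted p = 0.0029, adjusted p = 0.34 with an estimated correlation, and 0.072 without WT EGFP-positive replicate 2. The stress list had 0 calls of 21 (0 adjusted over the list alone, 1 higher unadjusted; 0.015, and adjusted p = 0.63 with an estimated correlation; 0.16 without WT EGFP-positive replicate 1), and its mean was 9.97 in the WT EGFP-negative array. The early activation list (0.32), B cell markers (0.32) and myeloid markers (0.15) were not called, but passed without WT EGFP-positive replicate 2 (0.0073), replicate 3 (0.0025) and replicate 2 (0.023), respectively. Without WT EGFP-positive replicate 2 and mutant EGFP-positive replicate 3 together early activation (0.00023) and myeloid markers (0.02) passed, and the follicular helper (0.062) and naive lists (0.092) did not. Median, mean and camera direction differed in sign for the cytotoxic, glycolysis, immature thymocyte and control lists, none of which was called.

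Across all probe sets limma called 496, of which 318 were higher and 178 lower in the WT EGFP-positive arrays, with 4236 at an unadjusted p under 0.05. The count was 287, 1193 and 259 without WT EGFP-positive replicates 1, 2 and 3, and 275 and 324 without mutant EGFP-positive replicates 1 and 2. It was 125 when only the 4 arrays of this comparison were fitted and 275 with Xist as a covariate.

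The same comparison for the mutant allele gave fewer calls. Foxp3 rose 35.1-fold, from 6.14 to 11.28 ± 0.21 (SD, n = 3; difference 5.13, SE 0.2, limma adjusted p = 0.00037). Il2ra rose by 1.72 (SE 0.2, 0.046), from 7.47 to 9.19 ± 0.22. Ntrk3, a neurotrophin receptor gene, fell by 2.54 (SE 0.17, 0.0061), and Atp1b1 fell by 2.13 (SE 0.18, 0.021). Pdlim4 fell by 2.35 (SE 0.22, 0.029) and Tdgf1, a growth factor co-receptor gene, by 3.4 (SE 0.29, 0.021), each in 3 of 3 arrays against the single EGFP-negative array. Other calls were Depdc1a (1.57) and Fnip2 (1.34) higher, and Efna5 (-2.44), Als2cl (-2.34), Rflnb (-2.08), Lyst (-1.87), Dzip1 (-1.83) and H2-Q2 (-1.8) lower. Except for Foxp3 and Ntrk3, each of these calls was lost without WT EGFP-positive replicate 1 (adjusted p 0.078 to 0.12), and each was also lost without at least 2 of the other EGFP-positive arrays in turn (up to 0.17). Over all alternatives the adjusted p of Il2ra ranged from 0.021 to 0.34 and that of Ntrk3 from 0.0045 to 0.27. Of the other probe sets of Ntrk3 the differences reached 0.06, and of Atp1b1 0.28. Of the panel, Ctla4 (1.69, 0.6), Ikzf2 (0.63, 0.25), Tnfrsf18 (1.11, 0.19), Pde3b (-1.17, 0.52), Il7r (-0.95, 0.71), Satb1 (-0.34, 0.65), Il2 (-1.21, 0.11), Ifng (0.7, 0.72), Il4 (0.62, 0.28), Il10 (1.53, 0.73), Gzmb (0.5, 0.41), Gata3 (0.63, 0.64) and Tbx21 (0.95, 0.48) did not pass.

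Of 46 genes known to be high in regulatory T cells 2 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 0.87; camera gave 2.5e-19, and adjusted p = 0.044 with an estimated correlation. Of 25 genes known to be low in these cells 2 fell, Atp1b1 and Rflnb, and 0 rose (13 and 0 adjusted over the list alone), with a median of -1.17 (4.3e-15, and adjusted p = 0.044 with an estimated correlation). All other calls were lost with an estimated correlation. The cell cycle list was such a call (9 rose adjusted over the list alone, median 0.8, 2.1e-18, and adjusted p = 0.33 with an estimated correlation). Naive genes were another (9 fell adjusted over the list alone, -0.86, 7.3e-11, and adjusted p = 0.16 with an estimated correlation). So were follicular helper genes (6 fell adjusted over the list alone, -0.72, 3.5e-06, and adjusted p = 0.16 with an estimated correlation) and suppressor genes (5 rose adjusted over the list alone, 0.57, 5.4e-07, and adjusted p = 0.16 with an estimated correlation). Interferon response genes were too (3 fell adjusted over the list alone, -0.46, 9.8e-07, and adjusted p = 0.33 with an estimated correlation). Cytotoxic (median 0.31, 0.0041, and adjusted p = 0.33 with an estimated correlation), Th1 (0.4, 0.0085, and adjusted p = 0.33 with an estimated correlation), T cell receptor signalling (-0.13, 0.0085, and adjusted p = 0.16 with an estimated correlation; 0.086 with gene means), glycolysis (0.24, 0.034, and adjusted p = 0.36 with an estimated correlation; 0.1 without mutant EGFP-positive replicate 2) and B cell lists (-0.48, 0.0023, and adjusted p = 0.36 with an estimated correlation) were called with the preset value. With all arrays fry gave an adjusted p of 0.035 for apoptosis genes, 0.035 for IL-2 and STAT5 targets and 0.046 for costimulatory receptors. Several lists not called by camera with all arrays passed when a single array was left out: apoptosis (0.023) and IL-2 and STAT5 targets (0.039) without WT EGFP-positive replicate 2, and Th17 (0.043) and costimulatory receptors (0.035) without WT replicate 1. So did IL-2 and STAT5 targets (0.03) and erythroid markers (0.03) without mutant EGFP-positive replicate 2, myeloid markers (0.025) without mutant replicate 1, and costimulatory receptors (0.037) without mutant replicate 3. Without WT EGFP-positive replicate 2 and mutant EGFP-positive replicate 3 together the stress (0.0013), apoptosis (0.0054), Th2 (0.015) and costimulatory lists (0.035) passed. Median, mean and camera direction differed in sign for the early activation, stress, NK and stroma lists, none of which was called with all arrays.

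Limma called 34 probe sets, 8 higher and 26 lower in the mutant EGFP-positive arrays, with 4381 at an unadjusted p under 0.05. The count was 4, 84 and 5 without WT EGFP-positive replicates 1, 2 and 3 and 9, 5 and 7 without mutant EGFP-positive replicates 1, 2 and 3, and of the genes named for this comparison Foxp3 and Ntrk3 passed each time, with adjusted p up to 0.0046 and 0.042. The count was 1 when only the 4 arrays of this comparison were fitted and 5 with Xist as a covariate.

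The EGFP-negative groups had 1 array each, so the allele difference in EGFP-negative cells was not tested. Gzmb stood at 5.31 in the WT array and at 11.78 in the mutant array, a difference of 6.47. Gzma differed by 5.63, Ccl3 by 5.12, the interferon-induced gene Ifitm2 by 4.86 and Gm4951 by 4.38, while Dapl1 (-3.74), Jchain, the immunoglobulin joining chain (-3.62), Xist (-3.61), Cd55 (-3.55) and Tent5a (-3.46) lay furthest in the other direction. In the panel, Ikzf2 differed by 3.5, Ctla4 by 3.18, Il4 by 3.05, Ifng by 2.74, Il10 by 2.24, Il2ra by 2.09, Foxp3 by 1.63, Il2 by 1.54, Tbx21 by 1.41, Tnfrsf18 by 0.74, Gata3 by 0.41, Pde3b by -0.57, Satb1 by -0.58 and Il7r by -1.12. The list of genes known to be high in regulatory T cells had a median of 1.98, with 34 of 46 genes at least 1 higher and 0 at least 1 lower, and the cell cycle list a median of 2.42; both medians exceeded those of all 10000 random lists of the same size and mean level (percentile 100). Medians were 1.25 for Th1, 1.31 for follicular helper and 1.64 for suppressor genes (percentile 100 each), 0.34 for cytotoxic genes (99.99), -0.71 for naive genes and -0.57 for genes known to be low in regulatory T cells (percentile 0 each). High percentiles were not specific to these lists. Medians were 0.71 for IL-2 and STAT5 targets, 0.63 for glycolysis, 0.56 for costimulatory and coinhibitory and 0.53 for interferon response genes (percentile 100 each). They were 0.62 for Th17 (99.99), 0.41 for early activation (99.99), 0.41 for Th2 (99.98), 0.26 for oxidative phosphorylation (99.96), 0.27 for homing (99.81) and 0.23 for cytokine receptor genes (98.92). Markers of other cells lay high too, myeloid genes at 0.21 (99.66) and NK genes at 0.25 (99.04). T cell receptor signalling (-0.13, 0.62) and stress genes (-0.12, 3.84) lay low. The remaining lists lay between percentiles 12.46 and 89.34, the control list at a median of 0.06 (53.2). In all, 2042 probe sets differed by at least 1, 1269 of them higher in the mutant array.

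**Figure D3:**
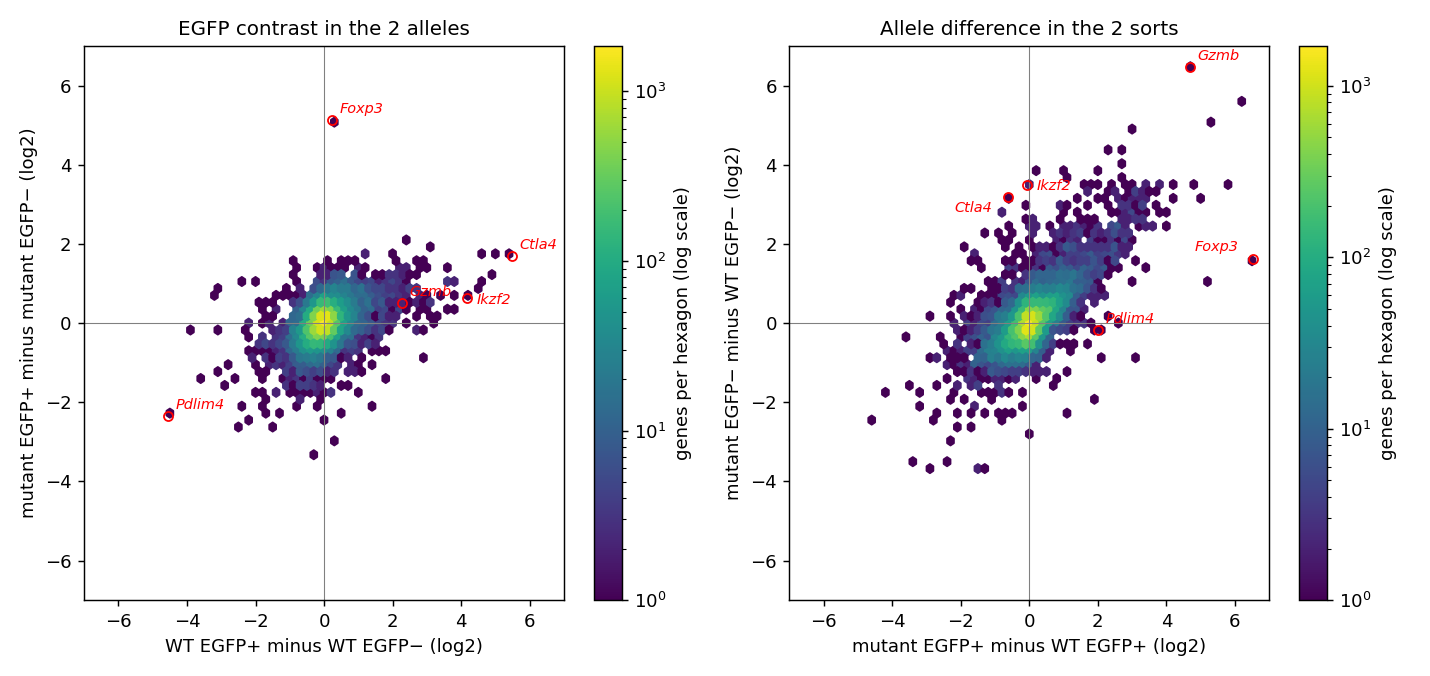
Log2 differences across genes, as hexagons coloured by the number of genes on a log scale. In the EGFP comparison of the mutant allele (vertical axis) against that of the wild-type allele (horizontal axis) r was 0.394, and in the allele difference of EGFP-negative (vertical axis) against EGFP-positive arrays (horizontal axis) r was 0.684; circled genes are named.

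Both EGFP comparisons shared no array, so their agreement was measured across genes, which are not independent replicates. Of the 318 probe sets higher in the WT comparison 278 (87.4%) differed in the same direction with the mutant allele, with median differences of 1.65 and 0.52; 3 were called in both, Il2ra, Cpd and Swap70, where independent lists would share 0.056. Both lists come from a single fit with 1 variance per probe set, which favours the same probe sets in both, so the values for independent lists are not what unchanged groups would share. Of the 178 lower 151 (84.8%) ran the same way, with medians of -1.52 and -0.53, and 14 were called in both (0.1 for independent lists). These 14 included probe sets of Pdlim4, Ntrk3, Als2cl, Dzip1, Lyst and Rflnb, and of Amigo2, Enc1, Klk1 and Nacc2, which were named after their values were seen. Over all genes the correlation was 0.394 (covariance 0.0573), against 0.00524 on average (-0.015 to 0.0331; covariance 0.000286) in simulated arrays without change, and 59.1% of genes had the same sign. The allele differences of the EGFP-positive and of the EGFP-negative arrays correlated at 0.684 (covariance 0.197; simulated 0.00899 and 0.000427), and 65.7% of all genes had the same sign (simulated 50.1%). These simulations drew each gene independently, so their ranges do not cover arrays in which genes vary together. In the real data, deviations from group means correlated at -0.153 to 0.121 between WT and mutant EGFP-positive arrays. The shares of the same sign were higher among called probe sets than over all genes. Of the 3308 probe sets higher in mutant EGFP-positive arrays 3149 (95.2%) were also higher in the mutant EGFP-negative array, with medians of 0.82 and 0.57, and of the 2426 lower 2056 (84.7%), with medians of -0.8 and -0.41.

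Whether the EGFP difference itself differed between alleles was tested as an interaction. Ikzf2 had a larger EGFP difference with the wild-type allele (4.18 against 0.63; interaction -3.55, limma adjusted p = 0.0044), and Foxp3 a larger difference with the mutant allele (5.13 against 0.24; 4.9, 0.0044). Il2ra differed by -2.85 (0.045). Limma called 18 probe sets, 7 higher and 11 lower, with 2766 at an unadjusted p under 0.05, and the test rested on 1 EGFP-negative array per allele. The count was 3, 85 and 2 without WT EGFP-positive replicates 1, 2 and 3 and 2, 2 and 3 without mutant EGFP-positive replicates 1, 2 and 3; of these fits Il2ra passed only that without WT EGFP-positive replicate 2 (up to 0.14 in the others), while Foxp3 (up to 0.043) and Ikzf2 (up to 0.05) passed each time. With Xist as a covariate the count was 2. Over all alternatives the adjusted p ranged from 0.001 to 0.11 for Foxp3, 0.00018 to 0.19 for Ikzf2 and 0.0084 to 0.22 for Il2ra.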

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

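The tests on the Foxp3 probe set, and leaving out arrays for the lists, were chosen after the results were seen; the interaction test and the count over splits were planned.

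The EGFP difference differed between alleles, by the test of the difference itself, for 18 probe sets. Named among them were Foxp3 (4.9), Trgv1, a gamma delta T cell receptor segment (3.52), Lrrc75b (2.89) and Gpr171 (2.14), each with a higher EGFP difference for the mutant allele, and Rragd (-3.82), Cd83 (-3.67), Ikzf2 (-3.55), Arhgap20 (-3.26), Cyp4f18 (-3.21), Il2ra (-2.85) and Tnfrsf4 (-2.62), each with a lower one. The limma adjusted p was 0.0044 for Foxp3 and Ikzf2 and 0.045 for the others of these genes. The differences are signed, so a higher one need not mean a rise with the mutant allele. Lrrc75b was among the largest falls in the WT EGFP comparison. Ikzf2 stood at 7.98 in the WT EGFP-negative array and at 11.48 in the mutant one. Its smaller EGFP difference with the mutant allele thus went with a higher EGFP-negative level. The calls of these genes other than Foxp3 and Ikzf2 were lost when WT EGFP-positive replicate 1 or 3 or any mutant EGFP-positive array was left out, when 2 or 3 probe sets in all were called (adjusted p of these genes 0.07 to 0.14). Further calls among the 18, at an adjusted p of 0.038 to 0.048, were probe sets of Trgv4 (3.22) and of Trgv4 with Trgv2 (3.73), so that 3 of the 7 higher calls were gamma delta T cell receptor segments. Other probe sets of Trgv4 differed by 2.952 (0.0612) and 0.622 (0.801). Cxcr6 was called at 4.59, while its other probe set differed by 4.017 (0.0612). Lower calls were Tnfrsf9 (-3.04), Tiam1 (-2.56), Icos (-1.83) and a probe set without a gene name (-2.45).

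As a group, genes known to be high in regulatory T cells had a smaller EGFP difference with the mutant allele (1 of 46 called higher and 5 lower, 1 and 32 adjusted over the list alone; median -1.55; camera adjusted p = 3.9e-44; adjusted p = 0.013 with an estimated correlation). The same held for cytokine receptors (-0.58; adjusted p = 0.03 with an estimated correlation) and costimulatory and coinhibitory genes (-0.64; adjusted p = 0.03 with an estimated correlation). Each list result of the interaction rests on 1 EGFP-negative array per allele. For genes known to be high in regulatory T cells, the median allele difference was -0.05 between the EGFP-positive groups. It was 1.98 between the single EGFP-negative arrays, which was not tested, so the smaller EGFP difference went with a higher EGFP-negative level. The other lists were called by camera with the preset correlation and lost with an estimated one. They were Th1 (0.5; adjusted p = 0.39 with an estimated correlation), Th2 (-0.34; 0.24), Th17 (-0.58; 0.1), follicular helper (-1.02; 0.065), suppressor (-0.92; 0.1), dissociation stress (-0.32; 0.46), naive (-0.46; 0.39), cell cycle (0.09; 0.66), homing (-0.43; 0.062), interferon response (-0.56; 0.32), IL-2 and STAT5 target (-0.62; 0.062) and myeloid marker genes (-0.46; 0.42), each adjusted p with an estimated correlation. With the preset correlation, single arrays decided the calls of cell cycle (0.27 without WT EGFP-positive replicate 2, 0.056 and 0.11 without mutant replicates 1 and 3, 0.15 without WT replicate 2 and mutant replicate 3), dissociation stress (0.11 without WT replicate 1, 0.22 without mutant replicate 3), naive (0.11 without WT replicate 1), Th1 (0.068 without WT replicate 1) and Th2 genes (0.076 without mutant replicate 3). Lists not called with all arrays passed without single arrays: early activation (0.0019), apoptosis (0.019) and T cell receptor signalling (0.025) without WT replicate 2, cytotoxic genes without WT replicate 3 (0.036) or mutant replicate 2 (0.032), B cell markers without WT replicates 1 (0.034) or 2 (0.036), erythroid markers without mutant replicate 2 (0.011), and genes known to be low in regulatory T cells without mutant replicates 1 (0.048) or 3 (0.022). Without WT replicate 2 and mutant replicate 3 together, early activation (0.00048), apoptosis (0.0064), T cell receptor signalling (0.024) and genes known to be low in regulatory T cells (0.025) passed, and with gene means apoptosis (0.0039) and T cell receptor signalling (0.033).

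The Foxp3 probe set read low in the arrays labelled WT EGFP-positive, between the 24.8 and the 31.3 percentile of all probe sets. The other 45 genes of the list known to be high in regulatory T cells lay above the WT EGFP-negative array by 2.65 to 2.69 on average in the 3 arrays. This argues against cells like those of the WT EGFP-negative array. The mutant EGFP-negative array also had a high mean of the whole list, 9.07 against 7.09 in the WT EGFP-negative array. EGFP-negative cells of another kind were therefore not excluded. Of the EGFP-positive arrays, 6 of 6 correlated better with the EGFP-negative array of their own label. This argues against an exchange of allele labels among the EGFP-positive arrays alone. The margins were narrow for WT EGFP-positive replicates 1 to 3 (0.9777, 0.981 and 0.9761 against 0.9706, 0.9766 and 0.9727). With 1 EGFP-negative array per label such an exchange was not excluded, and an exchange in all 4 groups stays open. A probe set outside the transcript of the tagged wild-type allele may give such a reading, and the difference of 0.24 (SE 0.2) could not settle this without probe positions and the allele's sequence. A biological effect of the allele on Foxp3 transcript stays open and untested.

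Between the EGFP-positive groups 5734 probe sets were called. The 10 splits of the 6 arrays are too few for a share under 0.05; 1 split, the real one, gave as many, and the highest other split gave 3.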

How the results depend on the processing

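Leaving out arrays for the lists and the agreement, leaving out a pair of arrays together and the covariates were chosen after seeing the data. Of the named genes' alternative values, 2063 kept direction and side of the threshold between the EGFP-positive groups, with 94 weaker, 16 stronger, 3 moved and 1 reversed; Ighm, -2.24, was 0.23 as the mean of its probe sets, which range from -2.6 to 2.11. For the WT EGFP comparison 1512 were the same, 103 weaker, 21 stronger and 17 moved, for the mutant one 1356, 104, 38 and 27, and for the interaction 1188, 85, 39 and 10. The causes of the changes below were not tested unless fewer samples or probe sets entered by construction. Without single arrays the counts of called probe sets ranged from 3355 to 7556 for mutant against WT EGFP-positive, 259 to 1193 for the WT EGFP comparison, 4 to 84 for the mutant one and 2 to 85 for the interaction; called lists ranged from 11 to 13, 13 to 15, 12 to 14 and 13 to 18. The agreement of 0.394 ranged from 0.361 to 0.402, and was 0.354 within title series 76. Without WT EGFP-positive replicate 2 and mutant EGFP-positive replicate 3 the counts were 7972, of which 45.5% were higher against 57.7%, and 4876 were shared with the full fit, then 1845, 325 and 171. With the stress list as a covariate the first was 3810; with Xist as a covariate the others were 275, 5 and 2. At least 2-fold, 1974 remained in the first; per gene mean it gave 3495 genes, and 84 and 37 in the mutant EGFP comparison and interaction. Those last comparisons gave 20 and 3 without dim probe sets, 64 and 55 with trend and robust settings, and 61 and 41 with array weights. The pseudocount gave 4 in the interaction, and only the arrays of the comparison 125 (WT) and 1 (mutant). Samples sharing the leading digits of their title numbers had deviations correlated at 0.121, 0.046 and -0.102, so these numbers were not taken to pair them; as a block they gave 83, 1 and 0 probe sets in the EGFP comparisons and interaction (limma, 2766 at an unadjusted p under 0.05 without the block), and as a random block 56 and 43 in the mutant EGFP comparison and interaction. With an estimated correlation camera called 0 (8 unadjusted), 6, 2 and 3 lists against 11, 14, 12 and 15, and with fry 20, 8 and 7 in the first, second and last comparison. No detection calls were used, so the limit set by signal over background was not measured.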

Other observations

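The tests of the 2 patterns at the end of this part were chosen after the results were seen, as were the sex-linked genes named here apart from Xist.

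None of the following lists passed camera between the EGFP-positive groups with all arrays, and its adjusted p closes each bracket. Fry, which does not compare with other genes, called Th2 (0.0035), Th17 (0.024), early activation (0.035), IL-2 and STAT5 (0.0017), apoptosis (0.024) and costimulatory genes (0.0028), not homing (0.52) or interferon response genes (0.99). Of 17 Th2 genes 4 rose and 3 fell (5 and 4 adjusted over the list alone; 0.74), with the cytokine Il13 at 1.62 and the chemokine receptor Ccr3 at -1.48. Of 13 Th17 genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; 0.87), the ligand-activated factor Ahr at 2.39 and Ccr6 at -2.21. Of 20 early activation genes 5 rose and 0 fell (6 and 0 adjusted over the list alone; 0.25), including Tnfsf14 (2.57) and the growth factor Csf2 (1.55). Of 29 homing genes 6 rose and 8 fell (8 and 9 adjusted over the list alone; 0.29), with the gut-homing receptor Gpr15 at -1.96. Of 28 interferon response genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; 0.6), led by Cxcl10 (2.66). Of 22 IL-2 and STAT5 targets 5 rose and 3 fell (8 and 5 adjusted over the list alone; 0.29), with the kinase Pim2 at 1. Of 25 apoptosis genes 6 rose and 2 fell (8 and 5 adjusted over the list alone; 0.87), among them the inflammatory caspase Casp4 (1.66), the death ligand Fasl (1.62) and Bak1 (1.12). Of 21 costimulatory and coinhibitory genes 5 rose and 3 fell (6 and 5 adjusted over the list alone; 0.87), with the inhibitory receptors Havcr2 at 3.33 and Cd160 at 2.45.

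Markers of other cells gave few calls there. Of 24 B cell genes 1 rose and 3 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.12, and 0.047 and 0.028 without WT EGFP-positive replicates 1 and 2), with Cd72 at -1.54, Bank1 at -1.09, H2-Ab1 at 1.23 and Ighm at -2.24, although Ighm lost its call without mutant EGFP-positive replicate 1 (0.052; 0.0043 to 0.66 over the alternatives) and its 10 other probe sets ranged from -2.6 to 2.11. Of 26 myeloid genes Cebpa rose (0.91; list 0.95), a call lost without any single mutant array (up to 0.079; 0.011 to 0.11 over the alternatives). The CD8 T cell list, with 2 genes, had a median of 0.93 and no test. Of 11 NK genes 2 rose (3 adjusted over the list alone; 0.29), among them Gzma, which the cytotoxic list also holds, and of 11 immature thymocyte genes Mns1 rose (1.26) and Rmnd5a fell (-0.68; 0.88). Of 14 stroma genes Krt18 rose (1.13) and Pecam1 fell (-1.07; 0.87), and limma called 0 of 10 erythroid and platelet genes (1 higher at an unadjusted p under 0.05; list 0.54). Of 27 ribosomal protein genes Rpl14 rose (0.73; 0.87), and of 12 control genes Gusb (1.16), Pgk1 (1.07) and Hprt (0.64) rose (0.43). Fry called the NK markers and the control genes upward (0.0035 each) and none of the other lists of this paragraph. For Treg-high, Th17, interferon, ribosomal, myeloid, thymocyte, stroma and costimulatory genes the median, mean and camera direction differed in sign.

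Xist, the transcript of the inactive X chromosome, read 9.81 in the WT EGFP-negative array and 11.43 in WT EGFP-positive replicate 3, against 6.06 to 7.05 in the other arrays, although the study's design text names male mice for the EGFP-positive cells. In WT EGFP-positive replicate 3 the Y-linked genes Eif2s3y (8.8), Kdm5d (6.85) and Uty (5.53) read lower than in the other arrays (10.01 to 10.5, 7.91 to 8.48 and 6.63 to 7.69).

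The allele difference of the EGFP-positive arrays was also seen between the EGFP-negative arrays. EGFP-positive cells carried into the mutant EGFP-negative sort would bring Foxp3 with the rest. Measured above the WT EGFP-negative array, 1.93% of the mutant EGFP-positive Foxp3 signal was found there. The genes compared were 584 called at least 1 higher in mutant than in WT EGFP-positive arrays. Each also lay at least 2-fold above the WT EGFP-negative array in the mutant EGFP-positive arrays. Of them, 5 had a share at or below that of Foxp3, and the median share was 52.2% (lower quartile 42.7%). The gap between this median and the Foxp3 share excludes carried-over cells with the Foxp3 level of the mutant EGFP-positive arrays as the whole source. Cells with less Foxp3, which could be sorted as EGFP-negative, were not excluded. CD8 T cells, which the CD4 sort would remove, stay possible in part: Cd8b1 differed by 0.05 and Cd8a by 1.81 (upper bound at 2 SE 3.23), and a pair of markers could not decide it. An effect of the allele, or of the animals that carry it, stays open and untested.

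The mean of the list of immediate-early and heat shock genes differed between arrays of one label, WT EGFP-positive replicate 2 and mutant EGFP-positive replicate 3 lying at -0.72 and -0.74 from their group means. Not every member followed: Hspa1b stood at 10.75 in that WT array, against 9.11 and 7.74 in the others. Of the 3 pairs of samples with the same leading title digits, 2 deviated in opposite directions, so the low means were not shared within a pair. The low arrays lay in different pairs, which alone gives these signs. An effect of handling on single samples was therefore not excluded. RNA degradation was not seen in the Gapdh and actin control probe sets. Their 3 prime over 5 prime difference in the low arrays exceeded the mean of the other arrays of their group by 0.07 at most. These control genes cannot speak for other transcripts, so degradation was not excluded. No biological explanation was tested.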
